A study of Mus musculus with 34 samples.

How the data were processed

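Total RNA of mouse neural stem cells was measured on 34 Illumina MouseWG-6 v2 arrays lying on 6 slides, with 200 ng of RNA per array. Per the labels, C17.2, an immortalised mouse neural stem cell line, and primary neural stem cells (NSC) from the telencephalon at embryonic day 13.5 received 1 of 4 retroviral treatments: the empty pBabe vector (control), a constitutively active STAT3 mutant (STAT3C), CEBPB, or STAT3C together with CEBPB. For the NSC arrays with both vectors the labels name STAT3 and CEBPB, without saying that this STAT3 is the active mutant. It was taken here as STAT3C, so NSC comparisons of both vectors with a single vector assume the same construct. Each C17.2 group holds 4 arrays. The NSC groups hold 5 control, 4 STAT3C, 4 CEBPB and 5 STAT3C+CEBPB arrays. The labels do not say which arrays come from separate cultures, so every p-value measures the spread between these arrays. No labels pair arrays between groups, and replicate numbers carry no order.

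The deposited file of each array gives, per the file headers, a mean bead signal for each of 45281 probes, which is an intensity on a linear scale. Values below 0 occur, so the authors' intensity values had background subtracted, although the notes do not say how. The deposited detection p-value of each probe runs from 0 to 1 and falls as the signal rises. The remaining columns per the file headers, the number of beads and the bead spread, are other quantities: the first was used only to describe precision and the second was not used here. The deposited series matrix holds the authors' normalised values on a log scale, read here as log2. Its transform and its method between arrays are not stated, and it served only as an alternative. The authors name BeadStudio and lumi, with no version of either. The values of all 34 array files were set against each other, and 0 pairs of arrays held identical values.

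Probes were joined to genes by the platform annotation and a RefSeq table of the GRCm38.p6 assembly, which gave 1 symbol for 34885 probes, several symbols for 18 and none for 10378. Only probes with 1 symbol were used. Signals were normalised for each cell type apart with neqc in limma 3.58.1 under R 4.3.3, which fits the background from the detection p-values, normalises by quantiles and takes log2 after an offset of 16. A probe was kept where its detection p was below 0.05 on at least 4 arrays of the cell type, and each gene was represented by its probe with the highest mean. This left 9699 genes in C17.2 and 10858 in NSC, and 11713 in a joint fit of all 34 arrays.

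Each gene was fitted with lmFit and eBayes of limma over the 4 groups of a cell type, with two-sided tests and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p below 0.05, and changes are log2 differences with their standard error (SE). The NSC fit held slide as a fixed term. Slide 4 held control and STAT3C arrays, slide 5 held CEBPB and STAT3C+CEBPB arrays, and slide 6 held all 4 groups, so NSC differences that cross slides rest on slide 6 and can depart from the plain difference of group means. In C17.2 slide 1 held the 4 controls alone, so a slide term could not be fitted with the controls, and slide and vector cannot be told apart in the C17.2 comparisons with control. Non-additivity is the change with both vectors minus the sum of the changes with each. The joint fit tested whether a change differed between C17.2 and NSC. A fold against a group in which no array detected the probe is given as a bound. For it, each such array was given the lowest normalised value of any probe detected on it, or the gene's own value where that was higher.

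There were 22 gene lists fixed before the data were examined: mesenchymal glioma genes, proneural glioma genes, module regulators, STAT3 target genes, C/EBP target genes, chemokines and cytokines, interferon-stimulated genes, MHC class I antigen presentation, contractile and SRF/TGF-beta genes, extracellular matrix and remodelling, neuronal differentiation, neural stem and radial glia, astrocyte, oligodendrocyte lineage, cell cycle, stress and amino acid response, cholesterol synthesis, glycolysis and hypoxia, microglia and macrophage, endothelial, pericyte and meningeal fibroblast, and erythroid. They were written from general knowledge, and some genes stand in several lists. Lists with at least 5 tested members were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. The erythroid list had too few tested members in both cell types, and the pericyte and meningeal fibroblast list in NSC.

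Named genes follow a rule also fixed before the data were examined. Stat3, Cebpb and 5 further regulators come first. For each comparison with control the rule takes up to 8 rises and 8 falls with the largest change among called genes whose arrays do not overlap between the groups, and for other comparisons up to 4 in each direction. It adds up to 4 called members of a list that passed its test and up to 2 in each direction of a list that did not. Clone names and predicted genes were passed over. Genes chosen after their values were seen are marked as such.

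The fit was tested on simulated data with the spread of these arrays: of 100 genes shifted by 1 on the log2 scale, between 32 and 96 were recovered depending on the comparison, of those shifted by 2 between 85 and 100, and a shifted list was recovered in every comparison. Between 1 and 19 unchanged genes were called. The noise was drawn apart for each gene, with no axis shared by arrays, no slide effect and no correlation within lists. These counts therefore do not show how the tests behave where the arrays hold such structure. On each array 33.8% to 41.7% of probes were detected, with a median of 43 to 45 beads per probe. The number of arrays limits the precision.

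Alternatives planned in advance were the deposited values, no background correction, cyclic loess, no filter and a stricter filter on detection (p below 0.01 on every array of a group), all probes in place of 1 per gene, array weights, a minimum log2 change of 1, slide as a random block, no slide term, slide as a fixed block over the transduced C17.2 groups, single slides alone, a fit on the groups of a comparison only, and leaving out each array in turn. For the lists, an estimated correlation and fry were also planned. Chosen after seeing the data were a division of slide 6 into 2 sets by detection of Xist, a fit without the 4 NSC arrays on which Xist was not detected, and a covariate from the mean of the chromosome with the largest spread over C17.2 arrays, and splits of the NSC arrays within slides beside those across slides. Without the 4 NSC arrays that lacked Xist, slide 6 holds only control replicate 5 and STAT3C+CEBPB replicate 5. These alone then link control and STAT3C, on slide 4, to CEBPB and both vectors, on slide 5. NSC differences across that link rest on 1 array against 1 in that fit, and their SE comes from the spread of other arrays. The probes of Stat3 and Cebpb were not set against the vector sequences. In tests of non-additivity and of differences between cell types, values of genes not detected in a group are limited by background and are marked as such. Principal components were computed on centred normalised values, and the mean of each chromosome's genes over arrays was set against 10000 random gene sets of its size. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.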

Results

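Transcript levels were measured on 34 mouse arrays, 16 of the C17.2 neural stem cell line and 18 of primary neural stem cells (NSC) from the embryonic telencephalon. Both cell types carried an empty retroviral vector, constitutively active STAT3 (STAT3C), CEBPB, or both factors. STAT3 and CEBPB are transcription factors of the response to cytokines, and the series asks how a module of such factors acts in mesenchymal transformation of brain tumours. Each C17.2 group had 4 arrays, and NSC had 5 control, 4 STAT3C, 4 CEBPB and 5 STAT3C+CEBPB arrays. C17.2 arrays detected 33.8% to 35.9% of probes and NSC arrays 36.3% to 41.7%. Within a group the correlation between arrays across all tested genes, which are not independent replicates, ran from 0.92 to 0.9865 in C17.2 and from 0.94 to 0.9977 in NSC.

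The arrays also differed in ways the vectors do not define. In C17.2 the first principal component held 50.2% of the variance, and arrays of each of the 3 transduced groups lay on both sides of its centre while the 4 controls lay on 1 side. The means of 16 of 20 chromosomes spread over the C17.2 arrays beyond all random gene sets, against 2 of 20 over the NSC arrays. In NSC, Xist, the RNA that coats the inactive X chromosome, was detected on every array of slides 4 and 5. It was not detected on 4 of the 6 arrays of slide 6, which were replicate 4 of each group. Those 4 arrays had Eif2s3y signals, from a gene on the Y chromosome, of 382.9 to 437.3, against -12.67 to 7.282 on the other NSC arrays.

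**Figure D1:**
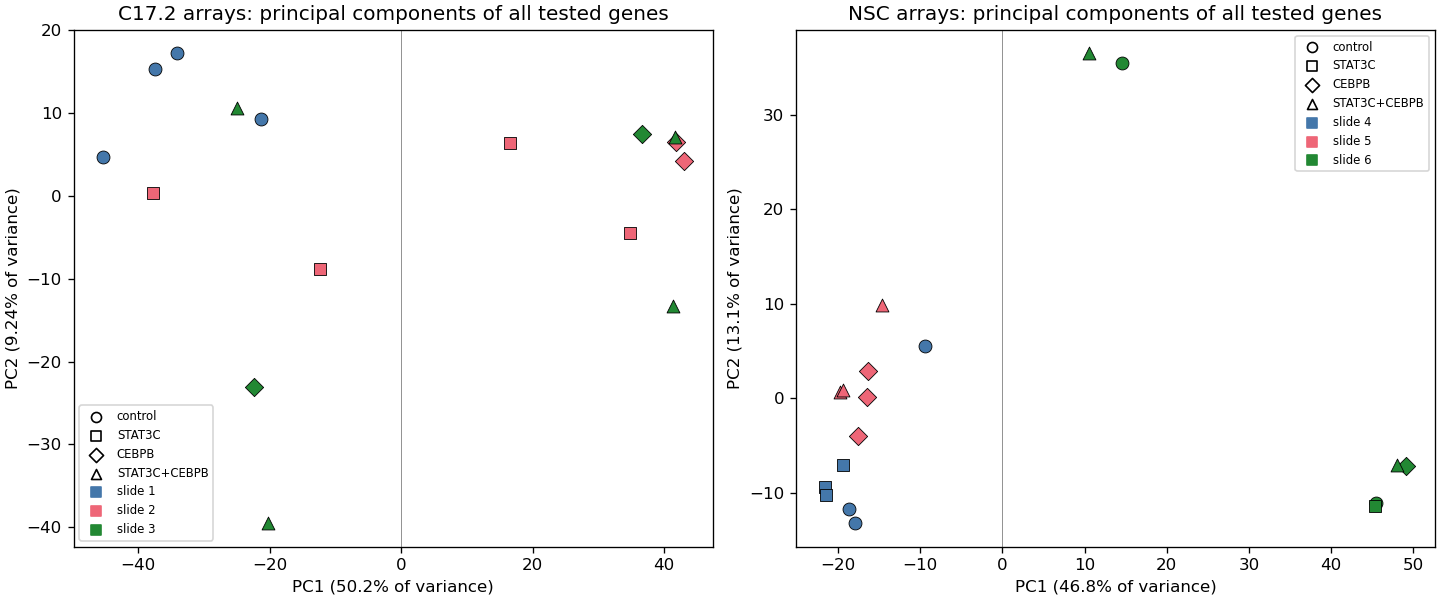
Principal components of all tested genes for the C17.2 and NSC arrays, 1 point per array, with the vector group as shape and the slide as colour. PC1 holds 50.2% of the variance in C17.2 and 46.8% in NSC, and in NSC the 4 slide 6 arrays without Xist lie together at 45.3 to 49.1.

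Neither Stat3 nor Cebpb passed the test in any comparison. Their probes were not set against the sequences of the vectors, so these values need not include transcripts from the vectors and do not measure the amount of either factor. Stat3 lies on chromosome 11 from 100886806 to 100939594 and Cebpb on chromosome 2 from 167688915 to 167690432 of GRCm38.p6. In C17.2 cells Stat3 averaged 9.59 ± 0.21 on the log2 scale (SD, n = 4) with the empty vector and 10.01 ± 0.12 with STAT3C, a difference of 0.42 (SE 0.35, adjusted p = 0.64), and all 4 STAT3C arrays lay above all 4 controls. With both vectors it averaged 9.25 ± 1.05, the widest SD of the 4 groups, a difference from control of -0.34 (SE 0.35, adjusted p = 0.638). STAT3C+CEBPB replicates 1 and 3 lay at 8.53 and 8.45, below all 4 controls at 9.29 to 9.79, and replicates 2 and 4 at 10.71 and 9.32. Cebpb averaged 9.89 ± 0.37 in control, 10.26 ± 0.33 with CEBPB (difference 0.38, SE 0.29, adjusted p = 0.466) and 10.59 ± 0.54 with both (difference 0.70, SE 0.29, adjusted p = 0.238). In NSC the change of Stat3 with STAT3C was 0.24 (SE 0.19, adjusted p = 0.875) and that of Cebpb with CEBPB was -0.38 (SE 0.21, adjusted p = 0.67). None of the 5 other regulators on the fixed list passed in any comparison with control.

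**Figure D2:**
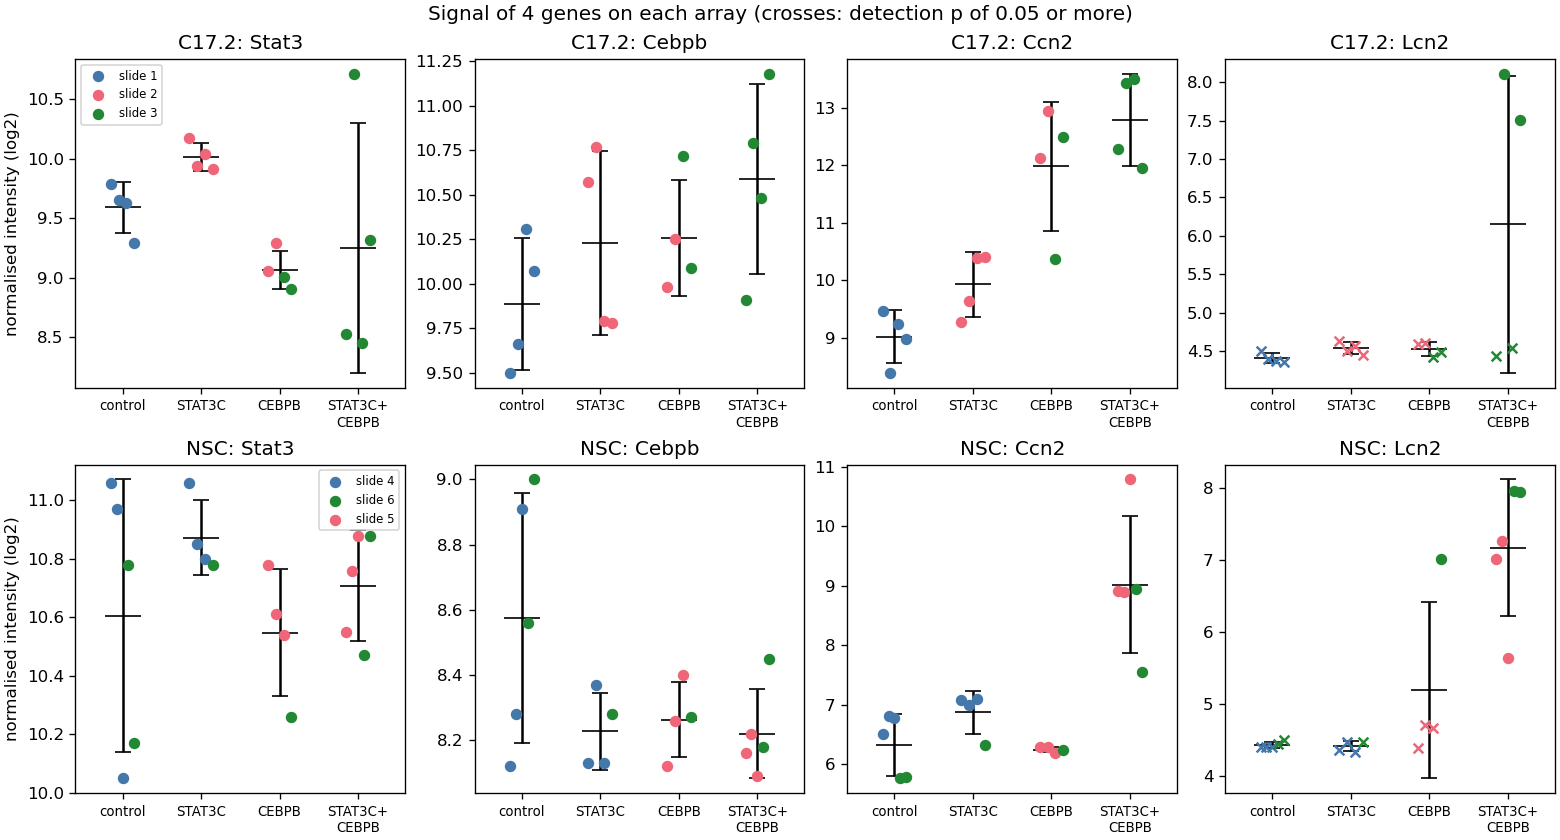
Normalised log2 intensity of Stat3, Cebpb, Ccn2 and Lcn2 on each array by vector group, for C17.2 (top) and NSC (bottom), with bars for the mean and SD and crosses where the probe was not detected. Ccn2 averages 12.80 with both vectors and 9.01 with the empty vector in C17.2 cells, and 9.01 and 6.32 in NSC.

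The first comparison asks what constitutively active STAT3 changes in C17.2 cells. Mgp, which encodes matrix Gla protein, a secreted inhibitor of calcification, rose by 2.80 on the log2 scale. It lies on chromosome 6 from 136872435 to 136875823. Its level went from 4.68 ± 0.30 in control (SD, n = 4), where 1 of 4 arrays detected it, to 7.48 ± 0.88 with STAT3C, where all 4 did (log2 difference 2.80, SE 0.36, adjusted p = 0.00917). It stood at 4.99 with CEBPB and 4.61 with both vectors. Of 9699 genes tested this 1 passed, and 1238 had an unadjusted p below 0.05 by limma, where about 5% would by chance. With each of control replicates 1, 2 and 4 and STAT3C replicate 2 left out the adjusted p of Mgp was 0.0614, 0.05, 0.0689 and 0.0656, and with the deposited values its change was 0.89 (adjusted p = 0.153).

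By camera, 7 of 21 lists shifted upward with STAT3C in C17.2 cells. All 18 tested genes of cholesterol synthesis had positive changes, with a median of 0.57 (adjusted p = 2.94e-10), and 11 of them passed when adjusted over the list alone, against 0 over all genes. The 55 mesenchymal glioma genes had a median of 0.30 and 37 positive changes (adjusted p = 6.77e-05), with 1 gene, Mgp, passing over all genes and 3 adjusted over the list alone. The 8 pericyte and meningeal fibroblast genes had a median of 0.90 (adjusted p = 0.000335), with Mgp up over all genes and 4 up adjusted over the list alone. STAT3 target genes had a median of 0.41 with 26 of 32 positive (adjusted p = 0.000335), and MHC class I antigen presentation 0.49 with 14 of 15 positive (adjusted p = 0.000176). Chemokines and cytokines had a median of 0.79 with 12 of 15 positive (adjusted p = 0.00258), and C/EBP target genes 0.43 with 9 of 12 positive (adjusted p = 0.0418). In these 4 lists 0 members passed either over all genes or over the list alone. With an estimated correlation none of the 7 held, with adjusted p from 0.0903 for the pericyte and meningeal fibroblast list to 0.368 for chemokines and cytokines. By fry, which tests whether a list's genes move on balance in 1 direction, the pericyte and meningeal fibroblast list alone passed (adjusted p = 0.00348).

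CEBPB alone changed 157 genes in C17.2 cells, 92 up and 65 down. The largest rise was of Atg9b, an autophagy gene, at 4.96 (SE 1.16, adjusted p = 0.0466), with a mean of 9.96 ± 1.79 with CEBPB (SD, n = 4) and detection on 1 of 4 control arrays. Gstm2, a glutathione transferase, rose by 4.18 (SE 0.73, adjusted p = 0.0168), and Tenm4 by 3.36 (SE 0.67), Arhgap29 by 3.13 (SE 0.65), Mfap3l by 2.66 (SE 0.50) and Rell1 by 2.50 (SE 0.59). Ccn2, a secreted matricellular protein, rose 7.85-fold from 9.01 ± 0.46 to 11.98 ± 1.13 (log2 difference 2.97, SE 0.50, adjusted p = 0.013), and P2ry14, a receptor for UDP-glucose, rose by 2.90 (SE 0.36, adjusted p = 0.00596). Among the falls, Pmp22, a protein of peripheral myelin, went from 10.40 ± 0.18 to 6.93 ± 1.02 (log2 difference -3.47, SE 0.47, adjusted p = 0.00596). The water channel Aqp1 went from 8.58 ± 1.62 to 5.21 ± 0.82 (log2 difference -3.36, SE 0.62, adjusted p = 0.0216). Adap1 fell by 4.31 (SE 0.98), Arhgef3 fell by 3.19 (SE 0.72), Acot1 fell by 3.09 (SE 0.74), Tst fell by 3.02 (SE 0.66) and Fbxo2 fell by 2.99 (SE 0.67). Lonrf3, at 7.60 in control, was detected on none of the CEBPB arrays and was at least 5.81-fold lower (adjusted p = 0.0168).

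Few members of the fixed lists passed with CEBPB in C17.2 cells. Of the 55 mesenchymal glioma genes 2 rose, Ccn2 and Itga7 (1.96, SE 0.32), a laminin receptor chain, and Col6a2, a chain of collagen VI, was at least 3.04-fold lower and detected on none of the 4 CEBPB arrays. The list itself did not pass (adjusted p = 0.0748). Sox9, a transcription factor of glial progenitors in the neural stem and radial glia and the astrocyte lists, rose by 2 (SE 0.46, adjusted p = 0.0431), and in both lists the other tested members did not pass. Camera placed 3 of 21 lists upward: cholesterol synthesis (18 of 18 positive, median 0.71, adjusted p = 9.46e-07, 10 up adjusted over the list alone), STAT3 target genes (median 0.35, 25 of 32 positive, adjusted p = 0.0383, 1 up adjusted over the list alone) and MHC class I antigen presentation (median 0.46, 11 of 15 positive, adjusted p = 0.0383, 2 up adjusted over the list alone). With an estimated correlation all 3 had an adjusted p of 0.505. The oligodendrocyte lineage list had a median of -0.51 and a mean of -1.40 over 7 genes (adjusted p = 0.108), with 3 down adjusted over the list alone. The glycolysis and hypoxia list had a median of -0.05 beside a mean of 0.21 (adjusted p = 0.866), and the astrocyte list -0.01 beside 0.13 (adjusted p = 0.622), with camera upward for both.

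On PC1, CEBPB replicates 1, 2 and 4 lay at 36.7 to 43, replicate 3 at -22.4 and the controls at -45.4 to -21.3. With the mean of chromosome 10, the widest in spread, as a covariate chosen after seeing the data, 0 of the 157 genes passed. That mean was -0.192 to -0.0969 in controls and -0.0709 to 0.282 with CEBPB. It can take up a vector effect, so lost calls do not tell vector from chromosome. All 157 kept their direction at a median of 0.74 of their change, and their median SE went from 0.25 to 0.29. P2ry14 went from 2.90 to 2.40 (SE 0.43, adjusted p = 0.0986), Pmp22 from -3.47 to -2.79 (SE 0.54, adjusted p = 0.137), Acot1 from -3.09 to -2.56 (SE 0.94, adjusted p = 0.486) and Atg9b from 4.96 to 2.02 (SE 0.88, adjusted p = 0.546). The count was 922 without CEBPB replicate 3 and 5 without replicate 1. Slide 1 held controls alone, so a slide effect cannot be told apart from these changes.

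Both vectors together changed 56 genes in C17.2 cells, 31 up and 25 down. Ccn2 rose 13.8-fold to 12.80 ± 0.80 (log2 difference 3.79, SE 0.50, adjusted p = 0.00283). Gch1, the first enzyme of tetrahydrobiopterin synthesis, rose by 3.43 (SE 0.71), P2ry14 by 2.97 (SE 0.36), Pcolce2, an enhancer of procollagen processing, by 2.51 (SE 0.40), Itga7 by 2.49 (SE 0.32), the adhesion molecule Nectin2 by 2.38 (SE 0.32) and Ralgps2 by 1.99 (SE 0.31). Vegfc, a growth factor of lymphatic vessels, was detected on 0 of 4 control and 4 of 4 STAT3C+CEBPB arrays and was at least 4.17-fold higher. Aqp1 fell by 3.64 (SE 0.62), Pmp22 fell by 2.46 (SE 0.47), Cavin4 fell by 2.20 (SE 0.29), Wwp2 fell by 1.66 (SE 0.20), Fam131b fell by 1.63 (SE 0.34) and Cdk5r1, an activator of the neuronal kinase Cdk5, fell by 1.59 (SE 0.24). Rnase4 and Luzp2, detected on none of the STAT3C+CEBPB arrays, were at least 3.84-fold and 3.70-fold lower. Adjusted p for these genes ran from 0.00215 for P2ry14 and Wwp2 to 0.0472 for Luzp2. Vldlr, a receptor for reelin and lipoproteins, was the 1 called gene of the stress and amino acid response list, at 1.34 (SE 0.28, adjusted p = 0.0472). The count ran from 15 without control replicate 1 to 432 without STAT3C+CEBPB replicate 1. With the chromosome 10 covariate 9 genes passed, and the 56 genes kept their direction with a median of 0.89 of their change. Gch1, Vegfc, Luzp2, Rnase4, Fam131b and Vldlr lost their calls with that covariate, with the deposited values and with no detection filter. With the covariate Gch1 stood at 3.15 (SE 0.83, adjusted p = 0.175), Fam131b at -1.11 (SE 0.31, adjusted p = 0.214) and Vldlr at 1.27 (SE 0.33, adjusted p = 0.175), and with the deposited values at 1.5, -0.58 and 0.83, while with no filter their values were unchanged. Vegfc, Luzp2 and Rnase4 had an adjusted p of 0.17, 0.17 and 0.113 with the covariate, and with 1 group at background their sizes were not compared. Ccn2, P2ry14, Itga7, Nectin2, Cavin4 and Wwp2 kept their calls in every fit. The controls lay alone on slide 1, so a slide effect cannot be told apart from these changes either.

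Camera placed 8 of 21 lists upward with both vectors in C17.2 cells. The interferon-stimulated genes had 17 of 18 positive changes with a median of 0.76 (adjusted p = 0.000767, 0 called over all genes or the list alone), and stress and amino acid response genes a median of 0.36 with 26 of 35 positive (adjusted p = 0.000767, 8 up and 1 down adjusted over the list alone). Contractile and SRF/TGF-beta genes had a median of 0.31 with 18 of 21 positive (adjusted p = 0.00323), where Ccn2 alone passed over all genes and 2 adjusted over the list alone. The mesenchymal glioma genes had a median of 0.36 with 2 up, Ccn2 and Itga7, and 9 up and 1 down adjusted over the list alone (adjusted p = 0.00936). STAT3 target genes (median 0.38, adjusted p = 0.00323), MHC class I antigen presentation (0.42, adjusted p = 0.00936), chemokines and cytokines (0.58, adjusted p = 0.0132) and cell cycle genes (0.21, adjusted p = 0.0306) had 0 members past the threshold over all genes and 3, 0, 3 and 0 adjusted over the list alone. Cholesterol synthesis had 9 positive and 9 negative changes, with a median of 0.01, a mean of -0.02 and camera downward (adjusted p = 0.826). With an estimated correlation no list held: 7 of the 8 had an adjusted p of 0.399 and cell cycle 0.604.

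Adding CEBPB to STAT3C in C17.2 cells changed 18 genes, 7 up and 11 down. Ccn2 rose by 2.86 (SE 0.50), Nectin2 by 1.73 (SE 0.32), Adam9, a membrane protease, by 1.34 (SE 0.20) and Tpd52 by 1.08 (SE 0.17). Aqp1 fell by 4.38 (SE 0.62), and the copper protein ceruloplasmin (Cp) fell by 3.31 (SE 0.59). Mgp and Pcdh19, detected on none of the STAT3C+CEBPB arrays, were at least 5.37-fold and 3.66-fold lower. Adjusted p for these genes ran from 0.00544 for Mgp to 0.0421 for Nectin2. Adding STAT3C to CEBPB changed 0 of 9699 genes by limma, with 388 at an unadjusted p below 0.05, and the test of non-additivity called 0, with 1045. With slide as a fixed block over the transduced groups Aqp1 alone of the 18 genes passed (-5.81, SE 0.50), and all 18 kept their direction with a median of 1.17 of their change, while their median SE went from 0.25 to 0.43. Ccn2 stood at 3.97 (SE 0.88, adjusted p = 0.367), Nectin2 at 2.28 (SE 0.60), Cp at -3.74 (SE 0.96), Tpd52 at 1.41 (SE 0.26) and Adam9 at 1.20 (SE 0.35), so these calls ended with wider SEs. Mgp and Pcdh19, at background with both vectors, had an adjusted p of 0.488 and 0.307. Without STAT3C replicates 2, 3 and 4 in turn the count was 4, 8 and 11.

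In NSC, STAT3C alone changed 0 of 10858 genes by limma, with 558 at an unadjusted p below 0.05 and a smallest adjusted p of 0.728. Camera placed 3 of 20 lists away from the rest. Glycolysis and hypoxia genes had 22 of 26 negative changes with a median of -0.35 (adjusted p = 4.17e-09, 3 down adjusted over the list alone). Cholesterol synthesis had 16 of 18 negative with a median of -0.14 (adjusted p = 0.00198), and stress and amino acid response genes 28 of 35 positive with a median of 0.11 (adjusted p = 0.00436), with 0 members past either threshold. With an estimated correlation their adjusted p was 0.112, 0.757 and 0.18. STAT3 target genes had a median of -0.01 (adjusted p = 0.545). Chemokines and cytokines had a median of -0.05, a mean of 0.02 and camera upward, the proneural glioma genes a median of 0.02 and the extracellular matrix and remodelling genes 0.01, both with camera downward, and all 3 had an adjusted p of 0.622. Without the 4 arrays that lacked Xist, a fit chosen after seeing the data, STAT3C changed 19 genes.

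CEBPB alone changed 3 genes in NSC. Lix1, on chromosome 17 from 17402686 to 17459387, went from 7.66 ± 0.24 in control (SD, n = 5) to 6.26 ± 0.10 (n = 4), a log2 difference with slide in the fit of -1.16 (SE 0.19, adjusted p = 0.043). Ccdc80 (-1.24, SE 0.15, adjusted p = 0.00331) and Cyth2 (1.03, SE 0.15, adjusted p = 0.0206) were the other called genes and were chosen after their values were seen, since their arrays overlap between the groups. All 3 also passed with both vectors, at -0.69 (SE 0.17), -0.97 (SE 0.14) and 0.88 (SE 0.14). The count was 8 with the deposited values, 1 with no slide term, 41 with slide 6 as 2 sets divided by Xist and 95 without the 4 arrays that lacked Xist, both chosen after seeing the data, and CEBPB replicate 4 held Lcn2 at 7.02 where the other CEBPB arrays held 4.39 to 4.71. Slide 6 was the only slide with both control and CEBPB arrays. Without the 4 arrays no slide held both, and the comparison ran through control replicate 5 and STAT3C+CEBPB replicate 5 alone. On slide 6 alone, with 1 CEBPB array against 2 controls, the difference of Lix1 was -1.36, and 1 array is too few to test the call.

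Camera placed 10 of 20 lists away from the rest with CEBPB in NSC, 9 downward and 1 upward, with 0 members called over all genes. Interferon-stimulated genes had 23 of 27 negative changes with a median of -0.44 (adjusted p = 7.46e-06, 2 down adjusted over the list alone), and MHC class I antigen presentation 15 of 16 negative with a median of -0.25 (adjusted p = 0.000638, 1 down adjusted over the list alone). Cholesterol synthesis (median -0.40, adjusted p = 0.000158), glycolysis and hypoxia (-0.16, adjusted p = 0.000715), STAT3 target genes (-0.11, adjusted p = 0.00113), module regulators (-0.38, adjusted p = 0.0145), extracellular matrix and remodelling (-0.18, adjusted p = 0.0174) and mesenchymal glioma genes (-0.13, adjusted p = 0.0236) had 0 members past either threshold. Neural stem and radial glia genes had a median of -0.19 (adjusted p = 0.025, 1 down adjusted over the list alone). The oligodendrocyte lineage list had 11 of 14 positive changes with a median of 0.36 (adjusted p = 0.00243), with 3 up and 1 down adjusted over the list alone. With an estimated correlation none held, with adjusted p from 0.0696 for STAT3 target genes to 0.404 for mesenchymal glioma genes, and by fry the oligodendrocyte lineage list passed (adjusted p = 0.0422). The 10 lists became 3 without CEBPB replicate 4, 5 without control replicate 5, 6 without STAT3C+CEBPB replicate 4 and 3 with no slide term. The C/EBP target genes had a median of -0.08, a mean of 0.01 and camera downward (adjusted p = 0.378).

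Both vectors together changed 308 genes in NSC, 164 up and 144 down. Lcn2 and S100a8, encoding a siderophore-binding protein of inflammation and a calcium-binding protein of myeloid cells, were detected on 0 of 5 control and 0 of 4 STAT3C arrays and on all 5 STAT3C+CEBPB arrays. Lcn2, on chromosome 2 from 32384637 to 32387739, stood at 7.17 ± 0.95 (SD, n = 5), at least 4.60-fold above control (fitted difference 3.74, SE 0.33, adjusted p = 2.83e-05). S100a8 stood at 6.59 ± 0.94, at least 3.09-fold above control (fitted difference 3.16, SE 0.32, adjusted p = 6.16e-05). With no slide term the fitted differences of Lcn2 and S100a8 were smaller, at 2.74 (SE 0.44, adjusted p = 0.00422) and 2.15 (SE 0.41, adjusted p = 0.0154). The size of each fitted difference is limited by background in control. Ccn2, on chromosome 10 from 24595442 to 24598683, rose 6.60-fold from 6.32 ± 0.52 to 9.01 ± 1.15 (log2 difference 2.72, SE 0.45, adjusted p = 0.00426). Hs3st1, a heparan sulfate sulfotransferase, rose by 1.97 (SE 0.34), the proprotein convertase Pcsk6 by 1.89 (SE 0.18), the homeobox gene Gbx2 by 1.78 (SE 0.34), Zbtb7c by 1.64 (SE 0.28) and the anion exchanger Slc4a2 by 1.61 (SE 0.22). Mmd2 fell by 3.18 (SE 0.76), Scrg1 fell by 3 (SE 0.30), Mgarp fell by 2.79 (SE 0.36), the chondroitin sulfotransferase Chst3 fell by 2.18 (SE 0.19), Ntn5 fell by 2.02 (SE 0.37), Fam71f2 fell by 1.85 (SE 0.29), the doublecortin-like kinase Dclk1 fell by 1.85 (SE 0.31) and Ppp1r3c, which directs a phosphatase to glycogen, fell by 1.83 (SE 0.38). Adjusted p for these genes ran from 2.83e-05 for Lcn2 and Chst3 to 0.0368 for Mmd2. With no slide term 6 of these falls lost their calls with smaller changes: Mmd2 stood at -2.36 (SE 0.68, adjusted p = 0.0883), Scrg1 at -1.95 (SE 0.51, adjusted p = 0.0607), Mgarp at -1.57 (SE 0.41, adjusted p = 0.0607), Ntn5 at -1.25 (SE 0.34, adjusted p = 0.0679), Fam71f2 at -0.98 (SE 0.31, adjusted p = 0.125) and Ppp1r3c at -0.99 (SE 0.34, adjusted p = 0.163). Hs3st1 stood at 1.32 without the 4 arrays that lacked Xist, where only replicate 5 sets STAT3C+CEBPB against control on the same slide. Mmd2 lost its call in 18 of 30 alternatives.

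Glycolysis and hypoxia genes fell together with both vectors in NSC. Of 26 tested members 10 fell over all genes, 24 had negative changes and the median was -0.61 (adjusted p = 2.84e-12), and 15 were down and 1 up adjusted over the list alone. Ankrd37 fell by 2.07 (SE 0.40), the vascular growth factor Vegfa fell by 1.59 (SE 0.22), the collagen prolyl hydroxylase P4ha2 fell by 1.53 (SE 0.26) and the pyruvate dehydrogenase kinase Pdk1 fell by 1.40 (SE 0.34). This was the only list whose call held with an estimated correlation (adjusted p = 0.0406), and it passed by fry (adjusted p = 0.000962). Ddit4 of the stress and amino acid response list fell by 0.98 (SE 0.22) and P4ha1 of the extracellular matrix and remodelling list fell by 0.89 (SE 0.21), while Ppp1r15a and Sesn2 of the stress list rose by 0.70 (SE 0.17) and 0.66 (SE 0.16). Neither of those lists passed (adjusted p = 0.331 and 0.62). With no slide term Ankrd37 stood at -1.18 (SE 0.49, adjusted p = 0.273) and Vegfa at -0.89 (SE 0.25, adjusted p = 0.0788), so these calls ended mainly with smaller changes. Without the 4 arrays that lacked Xist Vegfa stood at -1.13 and Pdk1 at -0.89. In that fit only replicate 5 sets STAT3C+CEBPB against control on the same slide. STAT3C replicate 4 stood apart from its group for Ankrd37, Vegfa and Pdk1. Ddit4, P4ha1, Ppp1r15a and Sesn2 lost their calls with no slide term, at -0.77 (SE 0.40), -0.54 (SE 0.23), 0.58 (SE 0.19) and 0.27 (SE 0.17). Without the 4 arrays they stood at -1.02, -0.83, 0.60 and 0.59.

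Several genes of glia fell with both vectors in NSC. In the astrocyte list 3 of 28 genes fell and 0 rose: the water channel Aqp4 fell by 1.77 (SE 0.41), the growth factor receptor Fgfr3 fell by 1.49 (SE 0.35) and Ndrg2 fell by 0.96 (SE 0.19). The list had a median of -0.24 (adjusted p = 0.00993), with 7 down adjusted over the list alone, but an adjusted p of 0.293 with an estimated correlation and 0.0456 by fry. Sox2, a transcription factor of neural stem cells in the proneural glioma list, fell by 0.98 (SE 0.23), and Mbp, a myelin protein of the oligodendrocyte lineage list, fell by 1.07 (SE 0.15), though 2 of 5 control and 2 of 5 STAT3C+CEBPB arrays detected Mbp. With no slide term Mbp stood at -0.29 (SE 0.29, adjusted p = 0.753), Aqp4 at -1.20 (SE 0.32, adjusted p = 0.0687), Fgfr3 at -1.16 (SE 0.43, adjusted p = 0.197), Ndrg2 at -0.45 (SE 0.18, adjusted p = 0.264) and Sox2 at -0.85 (SE 0.22, adjusted p = 0.0564). Without the 4 arrays that lacked Xist only replicate 5 sets STAT3C+CEBPB against control on the same slide. There Aqp4 stood at -0.78, Fgfr3 at -1.28, Ndrg2 at -1.08, Mbp at -0.78 and Sox2 at -1.14. Among the neuronal differentiation genes Crmp1 and Dpysl5 rose by 1.18 (SE 0.20) and 0.91 (SE 0.17), and Myt1, a zinc finger factor of neural cells, was detected on 0 of 5 STAT3C+CEBPB arrays and was at least 2.14-fold lower. Crmp1 and Dpysl5 were 0.59 (SE 0.21, adjusted p = 0.187) and 0.35 (SE 0.32, adjusted p = 0.729) with no slide term and 0.70 and 0.49 without the 4 arrays. The changes given here for these fits were smaller, apart from Sox2 and Ndrg2 without the 4 arrays, and several had wider SEs. Neither the neural stem and radial glia list (14 positive and 14 negative, adjusted p = 0.389) nor the proneural, oligodendrocyte lineage and neuronal differentiation lists passed, with adjusted p of 0.939, 0.48 and 0.939. The proneural median was 0.05 with camera downward.

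Contractile and SRF/TGF-beta genes had a median of 0.22 with both vectors in NSC, with 3 of 20 up, Ccn2, the actin cross-linker Actn1 (1.51, SE 0.29) and Pdlim7 (1.22, SE 0.23), and adjusted p of 0.0171 by camera and 0.506 with an estimated correlation. Cholesterol synthesis had a median of -0.51 (adjusted p = 0.000308, 5 down adjusted over the list alone) and cell cycle genes -0.17 with 35 of 45 negative (adjusted p = 0.0171), and these stood at adjusted p = 0.61 and 0.779 with an estimated correlation. Of the mesenchymal glioma genes 1 rose, Ccn2, and 1 fell, Vegfa, of 49 (median 0, adjusted p = 0.907). Of the STAT3 target genes 1 rose, Ptpn2 (0.79, SE 0.20), a phosphatase that acts on JAK and STAT proteins, and Vegfa fell (adjusted p = 0.437). Of the C/EBP target genes Lcn2 rose and the desaturase Scd1 fell by 0.76 (SE 0.19), with a median of -0.04 and a mean of 0.20 (adjusted p = 0.939). The endothelial list had 7 of 7 negative changes with a median of -0.19 (adjusted p = 0.0963) and passed by fry (adjusted p = 0.00162). The microglia and macrophage list did not pass in any comparison, with adjusted p of 0.225, 0.402 and 0.3 in C17.2 and 0.622, 0.39 and 0.939 in NSC for STAT3C, CEBPB and both vectors. With no slide term Actn1, Pdlim7 and Ptpn2 stood at 1 (SE 0.41, adjusted p = 0.264), 0.68 (SE 0.22, adjusted p = 0.133) and 0.70 (SE 0.41, adjusted p = 0.495), and without the 4 arrays that lacked Xist Actn1 and Scd1 stood at 0.81 and -0.96. With the arrays of control and STAT3C+CEBPB alone the 308 genes became 11, and on slide 6 alone, with 2 arrays against 2, they became 0. Both fits give the same differences, since only slide 6 holds both groups, and the main fit rests on slide 6 too. That all 308 kept their direction, with a median of 0.91 of their change, is therefore no separate check. Their median SE went from 0.18 to 0.23 and 0.25, so the calls ended with fewer arrays and wider SEs. On slide 6 alone the fitted difference of Lcn2 was 3.48 (SE 0.20, adjusted p = 0.154), Scrg1 stood at -2.57 (SE 0.42), Chst3 at -2.07 (SE 0.33) and Ccn2 at 2.47 (SE 0.49). The count was 199 with no slide term, of which 99 were among the 308, 385 without the 4 arrays that lacked Xist and 899 with slide 6 as 2 sets, and without STAT3C+CEBPB replicate 4, replicate 5 and CEBPB replicate 4 they were 566, 503 and 168. Ccn2 did not pass with the deposited values (1.21, adjusted p = 0.0826), and without those 4 arrays its change was 1.75. In that fit the groups share a slide only in replicate 5 of each, so its changes rest on that pair.

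**Figure D3:**
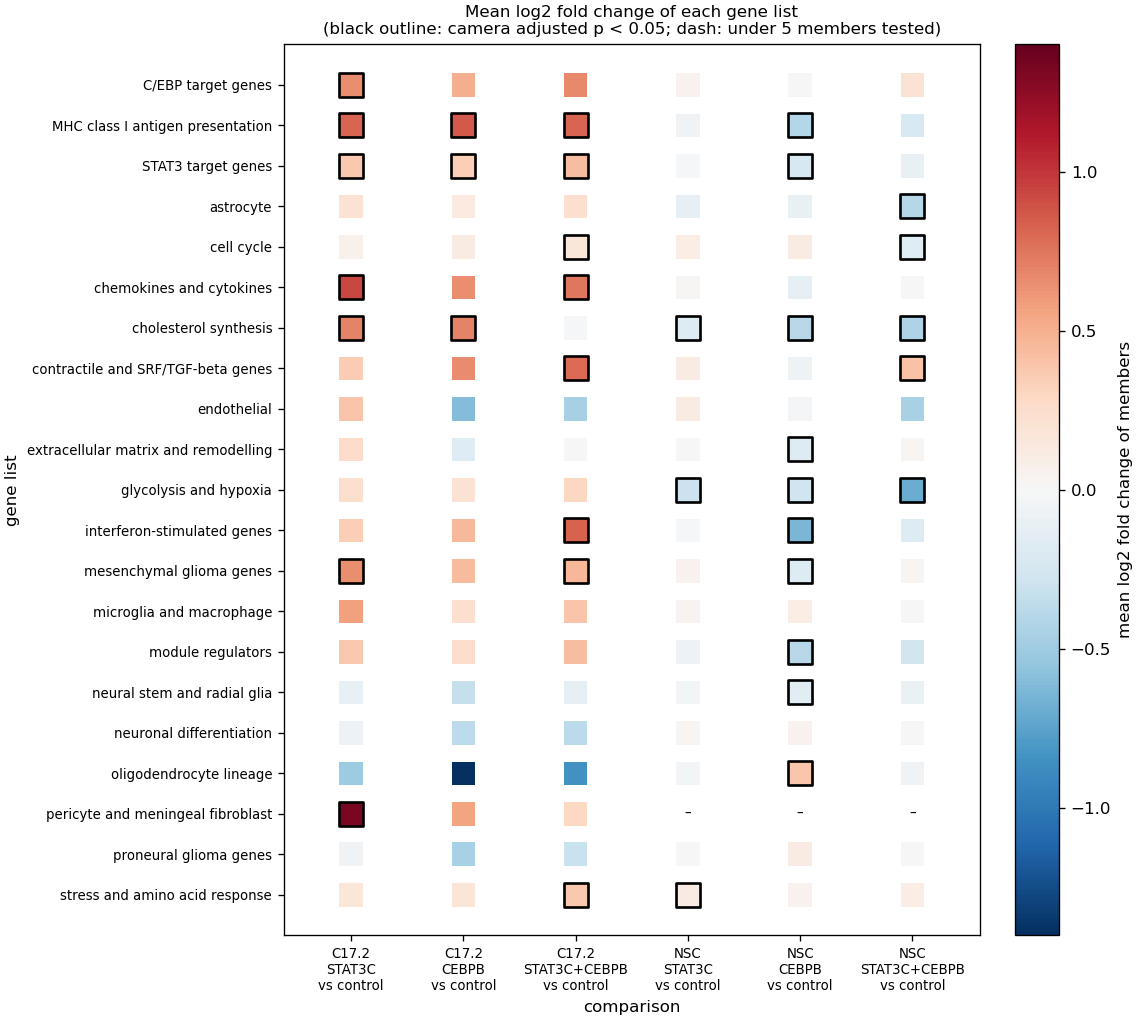
Mean log2 fold change of the tested members of each gene list (rows) in the 6 comparisons with control (columns), with a black outline where camera passed. In NSC with both vectors the glycolysis and hypoxia list has a mean of -0.70, and the oligodendrocyte lineage list in C17.2 with CEBPB has a mean of -1.40 with no outline.

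Adding CEBPB to STAT3C in NSC changed 37 genes, 18 up and 19 down. Lcn2 and S100a8 were at least 4.66-fold and 3.13-fold higher than with STAT3C alone (adjusted p = 0.000203 and 0.000467), and Hs3st1 and Sel1l3 rose by 1.81 (SE 0.37) and 1.59 (SE 0.30). Scrg1 fell by 2.42 (SE 0.32), Mgarp fell by 2.31 (SE 0.40), Scara3 fell by 1.96 (SE 0.36) and Chst3 fell by 1.68 (SE 0.21). With no slide term S100a8 did not pass (adjusted p = 0.0543), and Sel1l3, Scrg1, Mgarp, Scara3 and Chst3 stood at 0.79 (SE 0.32), -1.05 (SE 0.54), -0.88 (SE 0.43), -1.06 (SE 0.33) and -1.11 (SE 0.25), with adjusted p from 0.0877 for Chst3 to 0.558 for Scrg1. Without the 4 arrays that lacked Xist Hs3st1, Sel1l3 and Mgarp stood at 1.09, 1.13 and -1.42, so in both fits the changes given were smaller. In the second fit the slides are linked by replicate 5 of control and of STAT3C+CEBPB alone. The count was 3 without STAT3C replicate 4, 187 without STAT3C+CEBPB replicate 4, 13 with no slide term, 102 without the 4 arrays that lacked Xist and 225 with slide 6 as 2 sets.

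Adding STAT3C to CEBPB in NSC changed 702 genes, 350 up and 352 down, of which 108 changed at least 2-fold. Ccn2 rose by 2.89 (SE 0.35, adjusted p = 0.00042), Hs3st1 by 2.21 (SE 0.26) and Fam167a by 2.13 (SE 0.47), and the signalling protein Shh, detected on 0 of 4 CEBPB arrays, was at least 3.90-fold higher. Mmd2 fell by 2.75 (SE 0.59), Mgarp fell by 1.80 (SE 0.28) and Txnip, an inhibitor of thioredoxin, fell by 1.74 (SE 0.43), while Myt1 was at least 2.91-fold lower (adjusted p = 0.000212). On slide 5 alone, with 3 arrays against 3, 2125 genes passed, and without CEBPB replicate 2 and STAT3C+CEBPB replicate 4 the count was 230 and 1138. It was 101 with no slide term, where Mmd2 and Txnip stood at -3.04 (SE 0.72, adjusted p = 0.057) and -1.76 (SE 0.45, adjusted p = 0.0763), 1899 without the 4 arrays that lacked Xist and 1472 with slide 6 as 2 sets.

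Non-additivity was called for 4 genes in NSC, each at an adjusted p of 0.0435. With both vectors Zfhx2, Hs3st3a1 and Aak1 lay 1.64 (SE 0.27), 1.44 (SE 0.23) and 1.12 (SE 0.18) above the sum of the changes with each vector, and Necab2 lay at -0.95 (SE 0.15) against that sum. Necab2 was detected on 0 of 5 STAT3C+CEBPB arrays, so the size of its value is limited by background. All 4 calls were lost with no background correction, at 1.96 (SE 0.33), 1.58 (SE 0.25), 1.71 (SE 0.25) and -1.22 (SE 0.19) with adjusted p of 0.051 to 0.0571, and with cyclic loess, at 1.64 (SE 0.28), 1.42 (SE 0.22), 1.08 (SE 0.18) and -0.88 (SE 0.15) with an adjusted p of 0.0555. The calls thus ended at the threshold with changes of about the same or a larger size. With no slide term 0 genes passed, at 1.89 (SE 0.48), 1.39 (SE 0.27), 1.14 (SE 0.19) and -0.82 (SE 0.26) with adjusted p of 0.136 to 0.489, so there the SEs grew. The count was 189 with slide 6 as 2 sets, 670 without the 4 arrays that lacked Xist and 2423 with array weights, and between 0 and 222 with single arrays left out.

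The changes of the vectors were also correlated across genes, which are not independent replicates and share controls. In C17.2 the changes with STAT3C and CEBPB correlated at r = 0.78 over 9699 genes, where simulated unchanged groups against the same controls gave 0.50 and fits with the controls divided between the comparisons gave 0.62. The changes with CEBPB and with both correlated at 0.90, against 0.50 simulated and 0.75 with divided controls, and 23 rises and 18 falls were called in both, where independent lists would share 0.294 and 0.168. The simulation held no slide effect or axis shared by arrays, and all divided C17.2 controls lay on slide 1. Neither reference removes such sources from these values. In NSC the correlation of STAT3C with CEBPB was 0.44 (simulated 0.23, divided controls -0.04) and that of CEBPB with both 0.52 (simulated 0.73, divided controls 0.21). The 3 NSC genes called with CEBPB were called with both, in the same direction.

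The C17.2 line and the primary cells share no arrays. Across 9060 genes tested in both, the changes in C17.2 and NSC correlated at r = -0.03 for STAT3C, -0.11 for CEBPB and 0.04 for both vectors. With both vectors 50 genes in C17.2 and 240 in NSC were called among these, and 4 were called in both cell types: Ccn2 rose in both, Pmp22 and Fabp5 fell in both (Fabp5 fell by 1.20 in C17.2 and fell by 1.24 in NSC), and Serp2 fell by 1.24 in C17.2 and rose by 0.98 in NSC. Fabp5 and Serp2 were chosen after their values were seen. Independent lists would share 0.393 rises and 0.273 falls.

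The test of the difference between cell types called 1 gene for STAT3C, 46 for CEBPB and 147 for both vectors of 11713. The gene for STAT3C was Mgp, whose change was 2.78 higher in C17.2 than in NSC (SE 0.38, adjusted p = 0.000798) and which was detected on 0 NSC arrays of either group. For CEBPB, Gstm2 (4.68, SE 0.87), Arhgap29 (3.88, SE 0.81), Itga7 (3.10, SE 0.65) and Mfap3l (3.05, SE 0.69) changed more upward in C17.2, and Aqp1 (-3.44, SE 0.79), Pmp22 (-3.38, SE 0.58), Rnase4 (-2.78, SE 0.56) and Col6a2 (-2.36, SE 0.49) had lower values for C17.2. For both vectors the same held for Gstm2 (3.76, SE 0.82) and Itga7 (3.50, SE 0.62), and for Aqp1 (-3.77, SE 0.74), Rnase4 (-2.76, SE 0.53) and Cavin4 (-2.65, SE 0.50). Txnip (3.07, SE 0.79) changed by -2.35 in NSC and 0.73 in C17.2, Mmd2 (3.20, SE 0.78) fell in NSC, and S100a8 (-2.94, SE 0.36, adjusted p = 4.8e-05) rose in NSC and was detected on 1 of 4 STAT3C+CEBPB and 0 of 4 control arrays in C17.2. Several of these genes lay at background in 1 cell type, where a fall cannot be seen: Aqp1 was detected on 0 NSC arrays with CEBPB, both vectors or the empty vector, Rnase4 on 0 of 5 NSC controls, 3 of 4 NSC arrays with CEBPB and 1 of 5 with both vectors, and Mmd2 on 0 C17.2 arrays with both vectors or the empty vector. For Aqp1 and Mmd2 the values therefore show that the gene was not seen above background in 1 cell type with the empty vector, and not that its response differed. Rnase4 went from 4 of 4 to 0 of 4 C17.2 arrays with CEBPB, and in NSC, where a fall could not be seen, its change was 0.28 with CEBPB and 0.17 with both vectors. For Mgp and S100a8 they show only that no comparable rise was seen, with a size limited by background, and Col6a2 was detected on 0 of 4 CEBPB arrays in C17.2 and averaged 5.20 and 5.02 in NSC. With slide as a random block the 3 counts were 0, 3 and 2, and without C17.2 STAT3C replicate 1, CEBPB replicate 3 and STAT3C+CEBPB replicate 1 they were 103, 265 and 372.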

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

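The tests of the 3 patterns weighed here, their gene sets and thresholds, and the splits within slides were chosen after seeing the results. The gap test on single arrays, the tests between cell types and the counts over other splits were planned.

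Among the genes named in the report, some changes differed between C17.2 and NSC by the test of the difference itself. With STAT3C, Mgp changed 2.78 more in C17.2 than in NSC. With CEBPB the C17.2 change exceeded the NSC change for Gstm2 (4.68), Arhgap29 (3.88), Itga7 (3.10) and Mfap3l (3.05), and lay below it for Aqp1 (-3.44), Pmp22 (-3.38), Rnase4 (-2.78) and Col6a2 (-2.36). With both vectors it exceeded it for Gstm2 (3.76), Itga7 (3.50), Mmd2 (3.20) and Txnip (3.07), and lay below it for Aqp1 (-3.77), S100a8 (-2.94), Rnase4 (-2.76) and Cavin4 (-2.65). C17.2 controls lay alone on slide 1, so slide and vector were not separated there. Aqp1 (0 NSC arrays of the groups compared) and Mmd2 (0 C17.2 arrays) lay at background in 1 cell type, where a fall cannot be seen, so their values do not show a different response. Rnase4 was detected on 0 of 5 NSC controls, where a fall cannot be seen either, on 3 of 4 NSC arrays with CEBPB (NSC change 0.28) and on 1 of 5 with both vectors (0.17). For Mgp (0 NSC arrays) and S100a8 (1 of 4 and 0 of 4 C17.2 arrays) background limits the size.

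Among C17.2 arrays, 9 values stood far from the rest of their group. Each is given as the ratio of its gap to the range of the group, with its own value and the range of the others. In CEBPB replicate 3 these were Adap1 0.9 (7.15 against 4.68 to 4.93), Arhgef3 0.862 (5.66 against 4.42 to 4.59), Atg9b 0.832 (7.31 against 10.55 to 11.21) and PC1 0.904 (-22.4 against 36.7 to 43). The others were Adap1 0.897 (5.22 against 8.87 to 9.29) in STAT3C replicate 3, Cavin4 0.864 (6.37 against 5.56 to 5.67) in CEBPB replicate 4, median signal 0.857 (5 against 4.72 to 4.76) in CEBPB replicate 1, Luzp2 0.847 (5.69 against 7.25 to 7.53) in control replicate 3 and Ralgps2 0.979 (4.5 against 5.94 to 5.97) in control replicate 4. In all, 53 of 368 groups of values tested in C17.2 and NSC held such an array, where chance gives about 1 in 20, and the values share arrays.

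Among NSC arrays most such values lay in replicate 4 of STAT3C and CEBPB, the only slide 6 arrays of their groups. Control and STAT3C+CEBPB have replicates 4 and 5 there, and a gap test cannot flag an array that stands apart together with another. Control replicates 4 and 5 had median signals of 9.8 and 9.63, against 5.78 to 7.29 in the other controls, and were not flagged. The layout thus favours these arrays, and the values do not tie the gaps to the lack of Xist. In STAT3C replicate 4 they were Actn1 0.897 (6.81 against 8.72 to 8.93), Ankrd37 0.878 (8.12 against 5.49 to 5.81), Ccn2 0.874 (6.32 against 6.99 to 7.09), Chst3 0.909 (7.74 against 6.45 to 6.56), Crmp1 0.832 (5.38 against 5.96 to 6.08), Ddit4 0.862 (10.62 against 8.93 to 9.16), Fgfr3 0.854 (6.82 against 7.47 to 7.59), Mbp 0.876 (5.72 against 4.58 to 4.72), Mgarp 0.835 (7.64 against 6.16 to 6.4), Pdk1 0.879 (8.09), Pdlim7 0.876 (5.97 against 6.13 to 6.16), Ppp1r3c 0.875 (10.33 against 9.41 to 9.53), Ptpn2 0.846 (4.59 against 5.95 to 6.2), Scrg1 0.902 (8.93 against 6.25 to 6.51), Vegfa 0.869 (9.91 against 8.73 to 8.89), percent of probes detected 0.857 (38.1 against 40.5 to 40.9), median signal 0.849 (10.4 against 4.78 to 5.63) and PC1 0.967 (45.3 against -21.6 to -19.4). In CEBPB replicate 4 they were Aqp4 0.915 (5.15), Dclk1 0.887 (7.39 against 9.28 to 9.53), Ddit4 0.933 (10.47 against 9.46 to 9.52), Dpysl5 0.835 (6.75 against 4.75 to 5.08), Fam167a 0.986 (6.49 against 4.74 to 4.76), Fam71f2 0.901 (4.55 against 5.63 to 5.75), Gbx2 0.85 (8.1 against 6.99 to 7.15), Lcn2 0.878 (7.02 against 4.39 to 4.71), Mmd2 0.972 (5.74 against 9.88 to 10), Ndrg2 0.862 (5.77 against 6.15 to 6.21), Ntn5 0.936 (4.71 against 6.65 to 6.78), Pcsk6 0.941 (8.24 against 6.7 to 6.79), Ppp1r3c 0.98 (9.02 against 11.2 to 11.24), Ptpn2 0.887 (5.07 against 6.08 to 6.21), S100a8 0.967 (6.6 against 4.36 to 4.44), Scara3 0.842 (4.86 against 6.15 to 6.39), Slc4a2 0.961 (9.69 against 8.03 to 8.09), Txnip 0.923 (7.55 against 8.85 to 8.95), median signal 0.908 (10.3 against 4.53 to 5.06) and PC1 0.982 (49.1 against -17.6 to -16.4). The others were Dclk1 0.81 (9.35 against 8.64 to 8.77) and Ntn5 0.822 (7.3 against 6.02 to 6.25) in control replicate 5, Sox2 0.756 (9.48 against 8.41 to 8.67) in control replicate 3, and Hs3st1 0.764 (8.59 against 7.24 to 7.56), Dclk1 0.723 (7.15 against 7.63 to 7.82) and Ndrg2 0.844 (4.55 against 5.24 to 5.37) in STAT3C+CEBPB replicates 3, 4 and 5.

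The C17.2 arrays spread along 1 axis that cuts across the vector groups. Slides held 0.9% and vector groups 10.7% of the sum of squares of the 12 transduced arrays on PC1. This argues against either as the main source of the spread among those 12 arrays. The controls, alone on slide 1 and all at -45.4 to -21.3, were not in this test. It therefore does not bear on slide or vector in the comparisons with control. The means of 16 of 20 chromosomes spread over C17.2 arrays beyond every random gene set, so sublines with different chromosome dosage may underlie the axis. Eif2s3y, on the Y chromosome, had a signal of 1.166 in STAT3C+CEBPB replicate 2 against 79.58 to 932 on the other C17.2 arrays. DNA was not analysed here, and a programme of transcription shared by neighbouring genes was not tested.

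The NSC arrays of slide 6 stood apart from slides 4 and 5. Xist was not detected on 4 slide 6 arrays and was detected on every array of slides 4 and 5, which a hybridisation batch alone does not give. Cells of another culture on slide 6 may account for these 4 arrays, which carried Eif2s3y signals of 382.9 to 437.3 against at most 7.282 on the other NSC arrays. The labels name no sex or culture, so no biological explanation from the design was tested.

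NSC CEBPB replicate 4 carried part of the change seen with both vectors, with Lcn2 at 7.02 and S100a8 at 6.60. A swap with STAT3C+CEBPB replicate 4 would turn their difference round, but over 1899 genes its slope on the difference in the other NSC arrays was 0.21, with 69.9% of genes in the same direction. The slopes against control replicate 4 were 0.22 for CEBPB and 0.43 for STAT3C+CEBPB, a ratio of 0.51, so cells with both vectors in CEBPB replicate 4 and another culture with its own response to CEBPB cannot be told apart with 1 array. Over the 95 genes called with CEBPB without the 4 arrays the slopes against control replicate 4 were -0.01 for CEBPB and -0.05 for STAT3C+CEBPB. In that fit CEBPB is linked to control by replicate 5 of control and of STAT3C+CEBPB alone, so these slopes decide nothing. On the second Pgk1 probe CEBPB replicate 4 read 23.3, against 25.4 to 38.6 in the other CEBPB arrays, 15.5 to 25.6 with both vectors, 369 in control replicate 4 and 452 in STAT3C replicate 4.

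Other splits of the same arrays bear on whether the counts exceed what a random grouping gives. The real split called the most genes for CEBPB in C17.2 (157 genes, highest other split 0, 1 of 35 splits as large) and both vectors in C17.2 (56, highest 44, 1 of 35). A share of 1 of 35 is the smallest possible there, and shares were not adjusted over the comparisons, so chance is made less likely and not excluded. No split there keeps the controls apart on slide 1, so a slide effect stays open. In NSC, splits across slides gave as many genes in 4 of 100 for CEBPB (3, highest 764), 4 of 100 for both vectors (308, highest 1069), 3 of 100 for both against STAT3C (37, highest 109), 2 of 100 for both against CEBPB (702, highest 1115) and 3 of 100 for non-additivity (4, highest 1180). Such splits do not keep the groups of each slide, so splits within slides were set beside them. Within slides the share was under 0.05 for both against CEBPB (2 of 60), although another split called 1115, and not for non-additivity (8 of 100, highest 381). For CEBPB, both vectors and both against STAT3C slides allow only 3, 6 and 3 splits, too few for a share under 0.05, with the highest others at 764, 1069 and 754. For the cell type difference with both vectors (147, highest 175, 2 of 100) every split crosses slides as well, so chance and a slide effect stay open there too. The share was above 0.05 in C17.2 for STAT3C (1, highest 46, 2 of 35) and both against STAT3C (18, highest 737, 3 of 35). It was also above 0.05 for the cell type differences with STAT3C (1, highest 329, 17 of 100) and CEBPB (46, highest 169, 6 of 100). Every split reaches a count of 0, so the splits decide nothing for both against CEBPB in C17.2 (0, highest 25, 35 of 35), non-additivity in C17.2 (0, highest 282, 100 of 100) and STAT3C in NSC (0, highest 1905, 100 of 100, and within slides 60 of 60, highest 1). For the lists it was excluded in no comparison: STAT3C, CEBPB and both called 7, 3 and 8 in C17.2 (highest 11, 11 and 14, with 10, 14 and 10 of 35) and 3, 10 and 5 in NSC (highest 8, 11 and 9, with 48, 6 and 30 of 100). Splits that call several times the real count, such as 737, 764, 1180 and 1905, point to a structure of the samples: the split with 737 put STAT3C replicates 1 and 2 with STAT3C+CEBPB replicates 1 and 4, along the C17.2 axis, and that with 764 put control replicate 5 among CEBPB and CEBPB replicate 4 among controls, both on slide 6. By limma the 3 counts of 0, in the order above, had 388, 1045 and 558 genes at an unadjusted p below 0.05.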

How the results depend on the processing

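The division of slide 6 by Xist, the fit without its 4 arrays that lacked Xist and the covariate from chromosome 10 were chosen after seeing the data, and all other alternatives were planned. No paired analysis was possible because the labels carry no replicate numbers: those used here only name arrays. Of 119 calls of genes named in the report, each a gene in 1 comparison, 12 held under every alternative: Aqp1 in C17.2 both against STAT3C, Cavin4, Ccn2, Itga7, Nectin2, P2ry14 and Wwp2 in C17.2 with both vectors, and Ccn2, Hs3st1, Mgarp, Myt1 and Shh in NSC both against CEBPB. Over these calls 1801 values with 1 array left out kept the call and 523 lost it, and 920 and 323 under other alternatives, with 0 reversed. Mgp with STAT3C in C17.2 was 0.89 with the deposited values (adjusted p = 0.153) and 2.80 with the groups alone (adjusted p = 0.0781), and it also lost its call without control 1 (2.76), 2 (2.82) or 4 (2.71) or STAT3C 2 (2.67). With both vectors in NSC, Lcn2 was 3.48 on slide 6 alone (adjusted p = 0.154) and Ccn2 was 1.75 without the 4 arrays that lacked Xist. Without 1 array, 2 uncalled differences passed: C17.2 STAT3C+CEBPB vs STAT3C Stat3 was -1.25 without STAT3C+CEBPB replicate 2 (adjusted p = 0.0209), and C17.2 minus NSC STAT3C+CEBPB vs control Cebpb was 1.32 without C17.2 STAT3C+CEBPB replicate 1 (adjusted p = 0.0346). For every value that moved, the cause was not tested. Genes near background rest on few arrays above it.

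With the deposited values the counts were 0 for STAT3C and 35 for both vectors in C17.2, 8 for CEBPB (5 up, 3 down, 1 shared) and 10 for non-additivity in NSC (4 up, 6 down, 1 shared). In C17.2 both against STAT3C they called 7 up and 19 down, beside 7 and 11. Without background correction STAT3C and non-additivity in C17.2 gave 2 and 1, non-additivity in NSC 0, and the cell type differences with STAT3C and CEBPB 10 (5 up, 5 down) and 70. Cyclic loess gave 33 for both vectors in C17.2 and 0 for NSC non-additivity, and 2 up and 2 down for CEBPB in NSC beside 1 and 2. No scaling moved the median of all genes by over 0.1. Without a detection filter the counts were 71, 32 and 10 for CEBPB, both vectors and both against STAT3C in C17.2, and 7 and 0 for CEBPB and non-additivity in NSC. The stricter filter gave 280 for CEBPB in C17.2. With all probes, counted as probes, both vectors and both against STAT3C gave 121 and 34 in C17.2. In NSC all probes gave 7 for CEBPB, 495 for both, 1193 for both against CEBPB and 9 for non-additivity, and 223 for the cell type difference with both.

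Array weights gave 268, 2491 and 16 for STAT3C, CEBPB and non-additivity in C17.2. In NSC they gave 117 for STAT3C, 8 for CEBPB, 128 for both against STAT3C, 4231 for both against CEBPB and 2423 for non-additivity, and 582, 1482 and 410 for the cell type differences. A change of at least 1 left 102 for CEBPB in C17.2, 123 for both in NSC and 108 for both against CEBPB. Slide as a random block gave 3, 449 and 163 for STAT3C, CEBPB and both in C17.2 and 40 for both against STAT3C, 14 for both against STAT3C in NSC, and 0, 3 and 2 for the cell type differences. The correlation within C17.2 slides was -0.0373, and with the controls alone on slide 1 the first 3 counts are not adjusted for slide. With slide fixed over the transduced C17.2 arrays both against STAT3C gave 1. The chromosome 10 covariate gave 0, 9 and 38 for CEBPB, both and both against STAT3C in C17.2, and 4 lists for both, 3 up and 1 down. With the groups of a comparison alone the C17.2 counts were 0, 751, 33 and 1 for STAT3C, CEBPB, both and both against STAT3C. In NSC they were 5, 11, 13 and 359 for CEBPB, both, both against STAT3C and both against CEBPB.

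Without a slide term NSC gave 1, 199, 13, 101 and 0 for CEBPB, both, both against STAT3C, both against CEBPB and non-additivity, 3 lists for CEBPB and 3 for both, and 3 and 175 for the cell type differences with STAT3C and CEBPB. With slide 6 as 2 sets it gave 41, 899, 225, 1472 and 189 for the same 5, and 72 and 270 for the cell type differences with CEBPB and both. Without the 4 arrays that lacked Xist STAT3C gave 19 and the same 5 gave 95, 385, 102, 1899 and 670, and the cell type difference with CEBPB gave 27. In that fit only replicate 5 of control and of STAT3C+CEBPB links control and STAT3C to CEBPB and both vectors. Both against CEBPB on slide 5 alone gave 2125, and slide 6 alone gave 0 for both, with 2 arrays against 2. The lone STAT3C and CEBPB arrays of slide 6 do not allow a count. With an estimated inter-gene correlation the lists were 0, 0 and 0 in C17.2 and 0, 0 and 1 in NSC for STAT3C, CEBPB and both, and with fry 1, 0 and 0 in C17.2 and 0, 1 and 3 in NSC.

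Some small differences of Stat3 and Cebpb changed sign, and none passed where it did. C17.2 non-additivity of Cebpb (-0.01) was 0.02 with the deposited values, 0.01 with cyclic loess, 0.24 with array weights, 0.01 with slide as a random block and -0.21 to 0.21 with 1 array left out. C17.2 non-additivity Stat3 (-0.24) was 0.05 with the chromosome covariate and -0.72 to 0.03 with 1 array left out, and Stat3 in C17.2 both against CEBPB (0.19) was -0.30 to 0.45. With array weights Stat3 was -0.02 with STAT3C and -0.27 with both in NSC, 0.06 in NSC non-additivity and 0.06 in the cell type difference with both. Without the 4 arrays that lacked Xist Stat3 was 0.61 with CEBPB and 0.49 in both against STAT3C in NSC, and Cebpb in NSC both against STAT3C was 0.03 with the groups alone. With 1 array left out, Stat3 in NSC was -0.28 to 0.09 with CEBPB, -0.10 to 0.28 with both and -0.18 to 0.15 for non-additivity.

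Counts without single arrays follow, with the full count in brackets, the range, and arrays that moved it by over 1.5 times. C17.2 STAT3C vs control (1) gave 0 to 34: control 1 (0), 2 (0), 3 (2) and 4 (0), STAT3C 1 (34) and 2 (0), CEBPB 3 (2), STAT3C+CEBPB 1 (4) and 2 (2). C17.2 CEBPB vs control (157) gave 5 to 922: control 1 (13), 2 (44) and 4 (37), STAT3C 1 (328), CEBPB 1 (5), 2 (9), 3 (922) and 4 (53), STAT3C+CEBPB 1 (348), 2 (243) and 4 (243). C17.2 STAT3C+CEBPB vs control (56) gave 15 to 432: control 1 (15), 2 (20) and 4 (26), STAT3C 1 (89), 2 (35) and 4 (22), CEBPB 1 (31), 2 (35) and 4 (32), STAT3C+CEBPB 1 (432), 2 (16), 3 (16) and 4 (29). C17.2 STAT3C+CEBPB vs STAT3C (18) gave 4 to 26: STAT3C 2 (4), 3 (8) and 4 (11). C17.2 STAT3C+CEBPB vs CEBPB (0) gave 0 to 0. C17.2 non-additivity (0) gave 0 to 8: STAT3C 1 (8), STAT3C+CEBPB 2 (5). C17.2 STAT3C vs control gene lists (7) gave 6 to 8. C17.2 CEBPB vs control gene lists (3) gave 1 to 8: control 1 (5), 2 (1), 3 (8) and 4 (1), STAT3C 1 (5), 3 (6) and 4 (5), CEBPB 2 (1) and 3 (5), STAT3C+CEBPB 1 (5). C17.2 STAT3C+CEBPB vs control gene lists (8) gave 3 to 10: STAT3C+CEBPB 4 (3).

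The same counts follow for NSC and between cell types. NSC STAT3C vs control (0) gave 0 to 0. NSC CEBPB vs control (3) gave 1 to 16: control 3 (10) and 5 (12), STAT3C 1 (1) and 4 (5), CEBPB 2 (1) and 3 (1), STAT3C+CEBPB 3 (5), 4 (6) and 5 (16). NSC STAT3C+CEBPB vs control (308) gave 168 to 566: control 3 (505), STAT3C 1 (202), 3 (197) and 4 (197), CEBPB 2 (204) and 4 (168), STAT3C+CEBPB 4 (566) and 5 (503). NSC STAT3C+CEBPB vs STAT3C (37) gave 3 to 187: control 1 (24), 2 (19), 4 (23) and 5 (143), STAT3C 1 (13), 2 (11), 3 (17) and 4 (3), CEBPB 1 (16), 2 (19), 3 (20) and 4 (15), STAT3C+CEBPB 1 (17), 2 (18), 4 (187) and 5 (101). NSC STAT3C+CEBPB vs CEBPB (702) gave 230 to 1138: control 3 (1116), CEBPB 1 (318), 2 (230) and 3 (296), STAT3C+CEBPB 1 (311), 2 (308), 3 (415) and 4 (1138). NSC non-additivity (4) gave 0 to 222: control 1 (0), 2 (2), 3 (14), 4 (12) and 5 (8), STAT3C 1 (0), 2 (0), 3 (0) and 4 (0), CEBPB 1 (0), 2 (0), 3 (0) and 4 (222), STAT3C+CEBPB 1 (0), 2 (0), 3 (8), 4 (143) and 5 (42). NSC STAT3C vs control gene lists (3) gave 3 to 5: control 3 (5). NSC CEBPB vs control gene lists (10) gave 3 to 11: CEBPB 4 (3), STAT3C+CEBPB 4 (6), control 5 (5). NSC STAT3C+CEBPB vs control gene lists (5) gave 4 to 7. C17.2 minus NSC STAT3C vs control (1) gave 1 to 103: C17.2 control 3 (15) and 4 (4), C17.2 STAT3C 1 (103), C17.2 CEBPB 3 (6), C17.2 STAT3C+CEBPB 1 (5), 2 (2) and 3 (2). C17.2 minus NSC CEBPB vs control (46) gave 16 to 265: C17.2 control 1 (16), 2 (30) and 3 (88), C17.2 CEBPB 1 (16), 2 (18), 3 (265) and 4 (27), C17.2 STAT3C+CEBPB 1 (74), NSC CEBPB 2 (30) and 4 (19), NSC control 4 (20), NSC STAT3C+CEBPB 4 (27) and 5 (79). C17.2 minus NSC STAT3C+CEBPB vs control (147) gave 78 to 372: C17.2 STAT3C+CEBPB 1 (372), NSC CEBPB 4 (78), NSC STAT3C+CEBPB 5 (246).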

Other observations

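The tests on Pgk1 and the values of single arrays below were chosen only after results were seen. Lcn2, called with both vectors in NSC, was also read in C17.2 with both vectors, where it gave signals of 230.8 and 200.3 in replicates 2 and 4 and -4.661 and -0.5651 in replicates 1 and 3. On the other 12 C17.2 arrays Lcn2 lay between -10.43 and 4.559. Stat3 gave 1561 and 754.6 in replicates 2 and 4 and 314.9 and 317.6 in replicates 1 and 3. Cebpb gave 1645, 2678, 871.2 and 1376 in replicates 2, 4, 1 and 3, and Socs3 gave 1962 in replicate 2 and 450 to 563.8 in the others.

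Pgk1, a glycolytic enzyme on chromosome X from 106187100 to 106203699, has a second probe that was not the one kept for the gene. On it the NSC change was -3.26 with CEBPB (SE 0.36, adjusted p = 0.00127) and -3.61 with both vectors (SE 0.33, adjusted p = 4.17e-05), over all probes. With STAT3C it was -0.74 (SE 0.26, adjusted p = 0.858). The other Pgk1 probe gave -0.16 (SE 0.20) with CEBPB, -0.75 (SE 0.19) with both vectors and -0.35 (SE 0.14) with STAT3C. In C17.2 the second probe gave -1.06 (SE 0.43, adjusted p = 0.166) with CEBPB, -1.24 (SE 0.43, adjusted p = 0.178) with both vectors and 0.55 (SE 0.43, adjusted p = 0.615) with STAT3C. Its NSC signal was 15.5 to 38.6 with CEBPB or both vectors. On slide 4 it was 36.3 to 47.7 in the 3 STAT3C arrays and 133 to 161 in the 3 controls, and on slide 6 it was 452 in STAT3C replicate 4 and 369 and 245 in the controls. The tests on this probe were run first and then replaced by those on NSC CEBPB replicate 4. For a change of the Pgk1 transcript the test was the difference between the 2 probes with both vectors in NSC, 2.86 (SE 0.38), above the limit of 1 set for it, and by that limit the transcript alone did not account for the probe. For a vector sequence read by the probe it was the change in C17.2 with both vectors, -1.24, which left this open.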
